A study of Mus musculus with 6 samples.

How the data were processed

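Total RNA of cultured dermal cells from neonatal mice was hybridised to 6 one-colour Affymetrix arrays, 3 for DMSO and 3 for forskolin with RepSox. Per the labels' protocols, RNA was isolated with a column kit and labelled as biotinylated cRNA. The deposited table holds 1 log2 value for each of 35556 probe sets on each array. Per the submitters' processing notes, the authors made these values by RMA in the oligo package, with versions not given in the sources used here. RMA as usually run corrects the background, normalizes by quantiles between arrays and summarises the probes of a probe set on the log2 scale. That the values are log2 was checked from their range, and no further normalization was applied before the main test. The table had 0 missing values, and 0 of the 15 pairs of arrays were identical. Background correction could not be repeated from RMA values, and slide or scan batches were not analysed here. The arrays were grouped by their titles. The labels do not say whether the 3 samples of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

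Probe sets were named from the platform annotation: 21789 had 1 gene symbol, 1621 had several and 12146 had no listed gene. Of the probe sets with 1 symbol, 21698 were found by gene identifier in the GRCm38.p6 gene table, which changed 0 symbols. Probe sets with several symbols were left out of the gene tests. Where a gene had several probe sets, the brightest over all 6 arrays was used, which gave 19938 genes. Of the 999 such genes, 4 had another probe set that passed in the opposite direction. Of these, 0 are among the 136 genes taken by the rule for named genes. Further genes named in the text were not checked for this. Probe sets of closely related genes, such as the Ifit or Sprr genes, can share signal, so single members of such families are less certain. No genome coordinates are given, since the sources used here do not name the build of the array.

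Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, FR minus DMSO, two-sided, all 6 arrays, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. A 2-fold change means an absolute log2 change of at least 1 as well. No filter on dim values was used in the main test. The design, the 30 gene lists, the rule for named genes and all alternatives except cyclic loess were fixed before the data were examined. The lists cover targets of the pathways that the compounds act on, metabolic and stress programmes, muscle genes and markers of cell types that neonatal dermis can hold. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists, and again with the correlation estimated per list, with camera on ranks and with fry. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move on balance one way and fry mixed whether they change in either direction, and neither compares them with other genes. For each list, genes that passed were counted with the adjustment over all genes and over the list alone.

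The genes named are those with the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, with predicted and small RNA genes left out. To these were added up to 4 members of each list with the largest change among those that passed, and 15 genes fixed in advance, of which 1 was not analysed here. That rule took 136 genes. Setting their levels against those of olfactory receptor genes was chosen after the data were seen. Further members of a list are named where a small count or an exception called for it, and were chosen after their values were seen.

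The self-test simulated the comparison for 19938 genes with 200 changed. At the threshold it recovered 47% of those changed by 0.5 and 95% of those changed by 1 on the log2 scale, with 4 false calls among 146. Unchanged genes were drawn around the same mean in both groups. The 4 false calls therefore do not cover calls made through a shift that depends on level. Of 2 lists shifted by 0.3, camera found 2 with the preset correlation and 1 with the estimated one, and 0 other lists were called. Noise was drawn independently for each gene, so the self-test cannot show how camera behaves where the genes of a list are correlated. In the data the estimated correlation reached 0.619, for the interferon response genes. Alternatives tried were quantile normalization between arrays, centring on array medians, cyclic loess, a filter on dim genes, the mean of the probe sets of a gene, every probe set tested, a variance trend with robust moderation, array weights, a test against a log2 change of 0.5, ordinary variance without moderation, the replicate number as a block, and leaving out each array in turn. To set a change against those of genes of like level, 10000 random lists of equal size were drawn, each member replaced by a gene of similar mean level.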

Results

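Total RNA from dermal cells of neonatal C57BL/6 mice was profiled on 6 one-colour Affymetrix arrays after 2 days of culture. The labels name 3 arrays DMSO, after the solvent, and 3 arrays FR. The series design gives the treatment as forskolin and RepSox together, each at 20 µM. Forskolin activates adenylyl cyclase and so raises cyclic AMP, and RepSox inhibits the TGF-β type I receptor kinase. Expression is given as log2 RMA values, and each change is the FR mean minus the DMSO mean with n = 3 arrays per group. The median array value lay between 5.983 and 6.002 in DMSO and between 6.015 and 6.074 in FR. Across the 19938 genes tested, arrays correlated with r from 0.9956 to 0.9961 within DMSO and from 0.9926 to 0.9938 within FR. Between the groups r lay from 0.9717 to 0.9776, and genes are not independent replicates. The first principal component held 75.2% of the variance and separated the groups. The number of arrays limits the precision, and the median standard error of a log2 change was 0.0962.

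The comparison asks what the compound pair changed in dermal cells within 2 days. Genes of the contractile apparatus, of collagen and matrix, of the interferon response and of cholesterol synthesis were lower with FR, while adipocyte genes, keratinocyte markers, muscle differentiation genes and BMP and Id target genes were higher. These list results hold at a preset correlation between genes, and 0 of the 30 lists passed with an estimated one. The loss cannot be put down to correlation alone. For the inflammatory list the estimated correlation was 0.0111, near the preset 0.01, yet the unadjusted camera p went from 3.52e-05 to 0.0149. Of 19938 genes, 5559 (27.9%) changed at adjusted p under 0.05, 2671 higher and 2888 lower. A change of at least 2-fold was found for 624 of them, 325 higher and 299 lower, and 53 rose and 24 fell at least 4-fold. At unadjusted p under 0.05 the count was 7973. Olfactory receptor genes, taken as background, reached a level of 5.65 in DMSO at their 95th percentile. Of the 136 named genes, 19 had the mean of 1 group under that level, and their changes are written as at least the value found. Exceptions are the rises of Chrdl2, Wif1, Myog, Erg, Tyrp1 and Hdc, under 1 on the log2 scale, which are given as found. Such rises may be overstated, since olfactory receptor genes rose with FR as well (median log2 change 0.139). The means of both groups lay under the level of 5.65 for 10: Myf5, Nrarp, Prom1, Emcn, Tek, Nefl, Kit, Cd74, Fcer1g and Xist.

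The largest rise was that of Kera, which encodes the small leucine-rich proteoglycan keratocan. Its level went from 5.91 ± 0.17 in DMSO to 10.58 ± 0.17 in FR (mean ± SD, n = 3), a 25.5-fold rise (log2 change 4.67, SE 0.12, adjusted p = 9.29e-09). Igfbp4, which encodes an insulin-like growth factor binding protein, rose 12-fold, and Pappa2, a protease that cleaves such binding proteins, rose at least 8.64-fold, with log2 changes of 3.11, 3.46 and 4.07 on its 3 probe sets. Stc1, which encodes the glycoprotein hormone stanniocalcin, rose 9.18-fold. The adipocyte hormone gene Adipoq rose at least 8.30-fold, the angiotensinogen gene Agt 8.14-fold, and the matrix gene Sned1 7.98-fold. Reg3g, which encodes an antibacterial lectin, rose at least 7.43-fold, and Gfra2, a co-receptor gene for GDNF family ligands, 7.20-fold. Slpi, a protease inhibitor gene of epithelia, rose 7-fold, the albumin gene Alb 6.88-fold and the acute phase gene Saa3 6.78-fold. All 12 had adjusted p of 4.86e-07 or less.

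The largest fall was that of Itgbl1, an integrin beta-like gene, from 8.76 ± 0.105 in DMSO to 5.10 ± 0.33 in FR. It was at least 12.6-fold lower (SE of the log2 change 0.14, adjusted p = 7.13e-08). The interferon-induced gene Ifit3 was 8.63-fold lower and the collagen gene Col8a1 8.18-fold lower. Lrrc15, a membrane protein gene found on activated fibroblasts, was 7.20-fold lower, and Gask1b was 7.01-fold lower. Among other matrix and adhesion genes, Aspn was 6.93-fold lower, Mfap4 6.76-fold, Mfap5 6.54-fold and the collagen receptor gene Itga11 6.44-fold. Chodl was 6.86-fold lower, Mamdc2 at least 5.69-fold and the metalloprotease gene Adamts6 at least 5.38-fold. These 12 falls had adjusted p of 3.95e-07 or less.

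**Figure D1:**
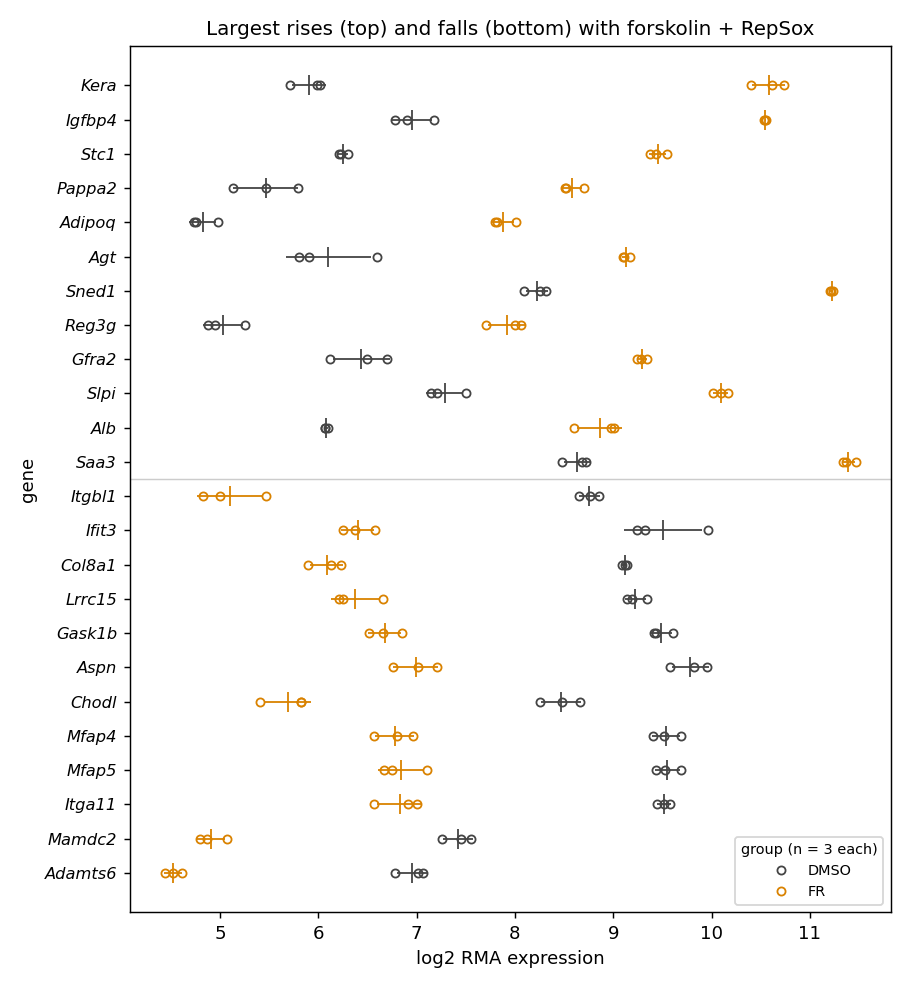
Log2 RMA expression of the 12 genes with the largest rise and the 12 with the largest fall, with 1 circle per array, the mean as a vertical tick and the SD as a horizontal bar (n = 3 per group). Kera moved from 5.91 to 10.58 and Itgbl1 from 8.76 to 5.10.

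The contractile genes of myofibroblasts and smooth muscle fell together. Of 20 measured, 17 fell and none rose, with the same counts when adjusted over the list alone, and the median change was -0.81 (camera adjusted p = 6.3e-13; adjusted p = 0.104 with an estimated correlation). Acta2, the smooth muscle actin gene that marks myofibroblasts, fell by 1.74 on the log2 scale (3.33-fold lower, adjusted p = 1.94e-07). The actin-binding gene Tagln fell by 1.94 and the LIM-domain gene Fhl2 by 2.04. The coactivator YAP and the transcription factor SRF respond to tension and actin. Their targets fell in 12 of 16 cases and rose in 1, also adjusted over the list alone (median -0.74, camera adjusted p = 7.51e-09, and adjusted p = 0.134 with an estimated correlation). Among them F3, the tissue factor gene, fell by 1.86, Ccn1 by 1.68, Ccn2 by 1.66 and the receptor kinase gene Axl by 1.64. The member that rose was Tead1, which encodes a DNA-binding partner of YAP (log2 change 0.66).

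TGF-β target genes were lower as a list. Of 23 measured, 15 fell and 4 rose (15 and 5 adjusted over the list alone), and the median change was -0.46 (adjusted p = 7.53e-06; adjusted p = 0.155 with an estimated correlation). Pmepa1, a feedback inhibitor gene of the pathway, fell by 1.89, Bhlhe40 by 1.71, Ccn2 by 1.66 and the SMAD corepressor gene Skil by 1.54. The inhibitory SMAD gene Smad7 fell by 0.44 (adjusted p = 0.00982). The 4 that rose were Snai2 (0.72) and Snai1 (0.39), both transcriptional repressors of epithelial genes, the cytokine gene Il11 (0.36) and the cell cycle inhibitor gene Cdkn2b (0.31). BMP and Id target genes moved the other way: 10 of 15 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.41, adjusted p = 0.000115; adjusted p = 0.198 with an estimated correlation). Id1 and Id2, which encode inhibitors of basic helix-loop-helix factors, rose 2.29-fold (adjusted p = 1.26e-05) and 2.18-fold, Atoh8 rose 2.47-fold, and the BMP antagonist gene Nog rose 1.68-fold. The single fall in this list was that of Smad7, which is also a TGF-β target.

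Collagen and matrix genes fell in 20 of 31 cases and rose in 6 (22 and 7 adjusted over the list alone), with a median of -0.515 (adjusted p = 1.35e-07; adjusted p = 0.154 with an estimated correlation). Col1a1, the main fibrillar collagen gene, fell from 10.35 ± 0.09 to 9.26 ± 0.16 (2.13-fold lower, adjusted p = 1.61e-05). Col8a1 fell by 3.03, P4ha3, which encodes a collagen prolyl hydroxylase subunit, by 2.32, and the crosslinking enzyme gene Lox by 1.68. Other matrix genes rose: Lum, a collagen-binding proteoglycan gene of the same family as Kera, rose by 2.17, Fbln1 by 1.03, Col3a1 by 0.66 and Dcn by 0.48. Matrix metalloproteinases and their inhibitors fell in 10 of 20 cases and rose in 5, also adjusted over the list alone (median -0.24, adjusted p = 0.0137; adjusted p = 0.337 with an estimated correlation and 0.103 by camera on ranks). Mmp11 fell by 1.92, the inhibitor gene Timp3 by 1.68, Mmp13 by 1.35 and the plasminogen activator gene Plat by 1.32, while Mmp3 rose by 1.05.

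Targets of cyclic AMP and CREB split. Of 26 measured, 10 rose and 5 fell (11 and 7 adjusted over the list alone), and the list did not pass the test (median 0.13, adjusted p = 0.198; adjusted p = 0.337 with an estimated correlation). It passed with dim genes left out (adjusted p = 0.0453) and by fry (0.00463), adjusted p reached 0.337 with an estimated correlation, and the median lay above the central 95% of random lists matched on level (upper end 0.115). Crem, which encodes cyclic AMP-responsive repressors, rose 2.12-fold (adjusted p = 3.03e-05), the GTPase gene Gem 2.89-fold, the coactivator gene Ppargc1a at least 2.56-fold (log2 changes of 1.36 and 0.73 on its probe sets) and the phosphodiesterase genes Pde10a 2.20-fold and Pde4d 1.36-fold (adjusted p = 0.00206). The orphan nuclear receptor genes went down: Nr4a3 was at least 2.30-fold lower (adjusted p = 1.6e-06), Nr4a1 1.38-fold lower (adjusted p = 0.00186) and Nr4a2 fell by 0.34. The 3 probe sets of Pde4d gave log2 changes of 0.44, 0.05 (adjusted p = 0.873) and 0.99.

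Muscle differentiation genes were higher with FR. Of 42 measured, 25 rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 0.435 (adjusted p = 3.49e-09; adjusted p = 0.134 with an estimated correlation). Actc1, the cardiac actin gene also used by embryonic skeletal muscle, rose 4.48-fold from a level of 6.57 (adjusted p = 9.21e-08). The fast troponin gene Tnnc2 rose 3.51-fold, the embryonic myosin gene Myh3 2.71-fold and the fast myosin light chain gene Mylpf 2.64-fold. Myog, the transcription factor gene of muscle differentiation, rose 1.46-fold (5.55 ± 0.14 to 6.10 ± 0.10, adjusted p = 0.00197). The member that fell was Mef2c, a muscle transcription factor gene (-0.71). Genes used by adult fibres differed: the fast myosin gene Myh1 rose by 0.84 and the skeletal actin gene Acta1 by 0.59, while log2 changes that did not pass were 0.15 for the creatine kinase gene Ckm, 0.02 for the myoglobin gene Mb and -0.02 for the fast myosin gene Myh4. Among myogenic progenitor genes, 9 of 17 rose and 1 fell, also adjusted over the list alone, and the list missed the threshold (median 0.33, adjusted p = 0.069; adjusted p = 0.245 with an estimated correlation). It passed with arrays centred on their medians (adjusted p = 0.0445), by camera on ranks (0.0368), by fry (0.0166) and without FR replicate 1 (0.044), and adjusted p reached 0.416 under another alternative. The satellite cell gene Pax7 rose by 0.33 (5.755 ± 0.10 to 6.09 ± 0.04, adjusted p = 0.0146), a call lost without DMSO replicate 2 (adjusted p = 0.0511) or 3 (0.0689). The myogenic factor gene Myf5 rose by 0.55 within the background range (4.42 to 4.96, adjusted p = 0.00601). Myod1, another such gene, rose by 0.49 (adjusted p = 0.0085). The BMP inhibitor gene Chrdl2 rose by 0.86, while Megf10, a receptor gene of satellite cells, fell by 0.81. Most of these genes were dim: the median DMSO level was 5.57 for the progenitor list and 5.68 for the differentiation list, against 6.21 for all genes. Both medians lay above the central 95% of random lists matched on level, whose upper ends were 0.223 and 0.167.

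Adipocyte genes rose in 13 of 18 cases and fell in 1 (15 and 1 adjusted over the list alone; median 0.79, adjusted p = 8.85e-10; adjusted p = 0.104 with an estimated correlation). Pparg, the master transcription factor gene of fat cells, rose 4.66-fold to a level of 10.24, the fatty acid binding protein gene Fabp4 5.41-fold to 11.36 and the fatty acid transporter gene Cd36 at least 4.85-fold from a level of 4.04. The fall was that of the fatty acid synthase gene Fasn (-0.40). Dermal papilla and condensate genes rose in 9 of 15 cases with none lower (10 adjusted over the list alone; median 0.375, adjusted p = 2.17e-05; adjusted p = 0.104 with an estimated correlation). Corin rose 2.55-fold, the alkaline phosphatase gene Alpl 2.40-fold, and Fgf10 2.20-fold, and Prom1 rose by 0.77 on the log2 scale within the background range. Fibroblast markers went both ways, with 8 of 19 higher and 8 lower, also adjusted over the list alone (median -0.03, adjusted p = 0.65; adjusted p = 0.742 with an estimated correlation). Lum and Dlk1 rose by 2.17 and 1.11 and Pi16 by at least 1.09, Mfap5 fell by 2.71, and the log2 change of the receptor gene Pdgfra was -0.03 (adjusted p = 0.802).

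Markers of another skin cell type moved with the treatment. Keratinocyte markers rose in 15 of 20 cases and fell in none, also adjusted over the list alone (median 0.82, adjusted p = 6.1e-10; adjusted p = 0.104 with an estimated correlation). Krt5, a keratin gene of basal keratinocytes, rose from 8.29 ± 0.16 to 10.46 ± 0.08 (4.52-fold), Krt16 4.08-fold, the desmosomal gene Perp 3.54-fold and Krt6a 3.10-fold. The mean level of the list was 5.87 to 5.98 in the DMSO arrays and 6.81 to 6.90 in the FR arrays. The inflammatory list, with Saa3 and Lcn2, moved up beside them, and Perp counts among the p53 targets as well.

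Markers of further cell types went both ways. Of 11 pericyte markers, 5 rose and 1 fell (5 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.0376; adjusted p = 0.28 with an estimated correlation). The potassium channel genes Kcnj8 and Abcc9 rose 3.35-fold and 2.48-fold, Steap4 rose 3.29-fold and the proteoglycan gene Cspg4 fell by 0.64. The pericyte call was lost without DMSO replicate 2 (adjusted p = 0.0541) and without FR replicate 3 (0.0669), and by camera on ranks (0.116), quantile normalization (0.0549) and cyclic loess (0.063), with adjusted p from 0.000799 to 0.28 over all alternatives, and the median lay inside the central 95% of random lists matched on level (-0.13 to 0.23). Neuronal genes rose in 6 of 16 cases and fell in 1, also adjusted over the list alone (median 0.16, adjusted p = 0.0175; adjusted p = 0.245 with an estimated correlation). The vesicle gene Snap25 rose at least 3.05-fold and Stmn2 2.48-fold, the neurofilament gene Nefl rose by 0.55 within the background range (3.94 to 4.49), and the tubulin gene Tubb3 was 3.29-fold lower. This call was lost with quantile normalization (adjusted p = 0.0706) and with cyclic loess (0.094), with a range of 0.0083 to 0.245 over all alternatives, and the median lay inside the matched random range (0.003 to 0.215). Endothelial markers rose in 4 of 18 cases and fell in 1 (5 and 2 adjusted over the list alone; median 0.18, adjusted p = 0.214; adjusted p = 0.514 with an estimated correlation). The VEGF receptor gene Flt1 was at least 4.34-fold lower, and Emcn and Tek rose by 0.68 and 0.54 within the background range and Erg by 0.46.

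Melanocyte markers rose in 5 of 10 cases and fell in 1, also adjusted over the list alone (median 0.27, adjusted p = 0.0512; adjusted p = 0.196 with an estimated correlation). The list passed with centring (adjusted p = 0.0445), the mean of probe sets (0.0358), camera on ranks (0.0298) and fry (0.0024), and without DMSO replicate 3 (0.0399), FR replicate 1 (0.0366) or FR replicate 2 (0.0456), with adjusted p of up to 0.257 elsewhere. The endothelin receptor gene Ednrb rose by 0.96, the receptor kinase gene Kit by 0.58 within the background range and the pigment enzyme gene Tyrp1 by 0.42. The melanocyte transcription factor gene Mitf fell by 1.19, while its other probe set did not pass (log2 change -0.06, adjusted p = 0.739). Of 13 Schwann cell and neural crest markers, 3 rose and 2 fell, also adjusted over the list alone (median 0.11, adjusted p = 0.634; adjusted p = 0.742 with an estimated correlation). Gap43 and Gfra3 rose by 0.48 and 0.36, and Cnp and Ncam1 fell by 0.33 and 0.28. The calls of Gfra3, Ncam1 and Cnp were lost under some alternatives, with adjusted p of up to 0.103, 0.109 and 0.06. Macrophage and leukocyte markers rose in 3 of 18 cases (2 adjusted over the list alone; median 0.16, adjusted p = 0.165; adjusted p = 0.603 with an estimated correlation), namely Cd14 by 0.91, Cd74 by 0.33 and Fcer1g by 0.32, with adjusted p of up to 0.0957 for Cd74 and 0.158 for Fcer1g over the alternatives. Mast cell markers rose in 2 of 10 cases, also adjusted over the list alone (median 0.19, camera adjusted p = 0.113). Adjusted p was 0.337 with an estimated correlation and 0.0158 by fry, which the list passed. The 2 that rose were Kit and, by 0.37, the histidine decarboxylase gene Hdc (adjusted p of Hdc up to 0.0733 over the alternatives). The 4 sex-linked genes did not pass as a list (median 0.08, adjusted p = 0.693; adjusted p = 0.742 with an estimated correlation). Xist rose by 0.26 (adjusted p = 0.047) at the dim levels of 3.97 and 4.23, and did not pass adjusted over the list alone or under some alternatives (adjusted p of up to 0.144).

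Interferon response genes had the lowest adjusted p of the lists with the preset correlation, but were not among the 9 lists at unadjusted p under 0.05 with an estimated one (p = 0.0616, correlation 0.619). Of 18 measured, 16 fell and none rose (17 fell adjusted over the list alone), with a median of -1.27 (adjusted p = 2.06e-14; adjusted p = 0.154 with an estimated correlation). Ifit3 fell by 3.11, Ifit1 by 2.32, Ifit2 by 1.70, and Ddx58, which encodes the RNA sensor RIG-I, by 1.66. Inflammatory cytokine and chemokine genes were higher as a list: 12 of 24 rose and 3 fell (13 and 4 adjusted over the list alone; median 0.33, adjusted p = 9.59e-05; adjusted p = 0.104 with an estimated correlation). The neutrophil chemokine genes Cxcl2 and Cxcl1 rose 4.58-fold and 2.71-fold and the lipocalin gene Lcn2 rose at least 5.13-fold. The macrophage growth factor gene Csf1 (-0.85), Ccl8 (-0.63) and Il1a (-0.47) fell.

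Metabolic and stress lists were lower. All 17 measured cholesterol synthesis genes fell, also adjusted over the list alone (median -0.55, adjusted p = 2e-11; adjusted p = 0.104 with an estimated correlation), led by Lss, Cyp51, Idi1 and Mvd, which fell by 0.98, 0.94, 0.79 and 0.78. Glycolysis genes fell in 9 of 17 cases with none higher, also adjusted over the list alone (median -0.34, adjusted p = 0.000268; adjusted p = 0.215 with an estimated correlation). The aldolase gene Aldoc fell by 1.81, the pyruvate kinase gene Pkm by 0.71, Eno2 by 0.48 and Pgam1 by 0.47. Of 19 genes of the unfolded protein and integrated stress responses, 8 fell and 1 rose, also adjusted over the list alone (median -0.22, adjusted p = 0.000703; adjusted p = 0.154 with an estimated correlation). Those that fell included the amino acid synthesis genes Asns by 1.33 and Psat1 by 1.03, Herpud1 by 0.84 and the transcription factor gene Atf4 by 0.75. The chaperone gene Hspa5 had a log2 change of -0.10 (adjusted p = 0.375). The median of this list lay inside the range of random lists matched on level (-0.226 to 0.119).

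Targets of p53 fell in 7 of 11 cases and rose in 1, also adjusted over the list alone (median -0.56, adjusted p = 0.000502; adjusted p = 0.126 with an estimated correlation). Eda2r fell by 0.96, Trp53inp1 by 0.92 and Zmat3 by 0.90, and the member that rose, Perp (1.82), is also a keratinocyte marker. Cell cycle genes fell in 14 of 36 cases and rose in 1 (15 and 1 adjusted over the list alone; median -0.13, adjusted p = 0.000337; adjusted p = 0.422 with an estimated correlation). Kif23, Cenpf and Tpx2, which act in mitosis, fell by 0.91, 0.82 and 0.66, Rrm1, which supplies nucleotides for DNA synthesis, by 0.71, and the proliferation marker Mki67 by 0.43 (adjusted p = 0.00484). The median of this list lay at the 20.3 percentile of 10000 random lists of equal size matched on level.

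Wnt target genes rose in 4 of 14 cases and fell in 4, also adjusted over the list alone (adjusted p = 0.812; adjusted p = 0.813 with an estimated correlation). Their median change was 0.19, while their mean was -0.09 and the test pointed down. The list passed by fry (adjusted p = 0.0219), and adjusted p reached 0.958 under another alternative. Nkd2, Dkk3 and the stem cell receptor gene Lgr5 fell by 1.22, 1.14 and 1.13, and the Wnt inhibitor gene Wif1 rose by 0.66. Notch target genes rose in 3 of 11 cases and fell in 1, also adjusted over the list alone (median 0.11, adjusted p = 0.55; adjusted p = 0.742 with an estimated correlation). Hes1 fell by 1.08, and Hey1, Dtx4 and Nrarp rose by 0.61, 0.56 and 0.41, the call of Nrarp being lost under some alternatives (adjusted p of up to 0.163).

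**Figure D2:**
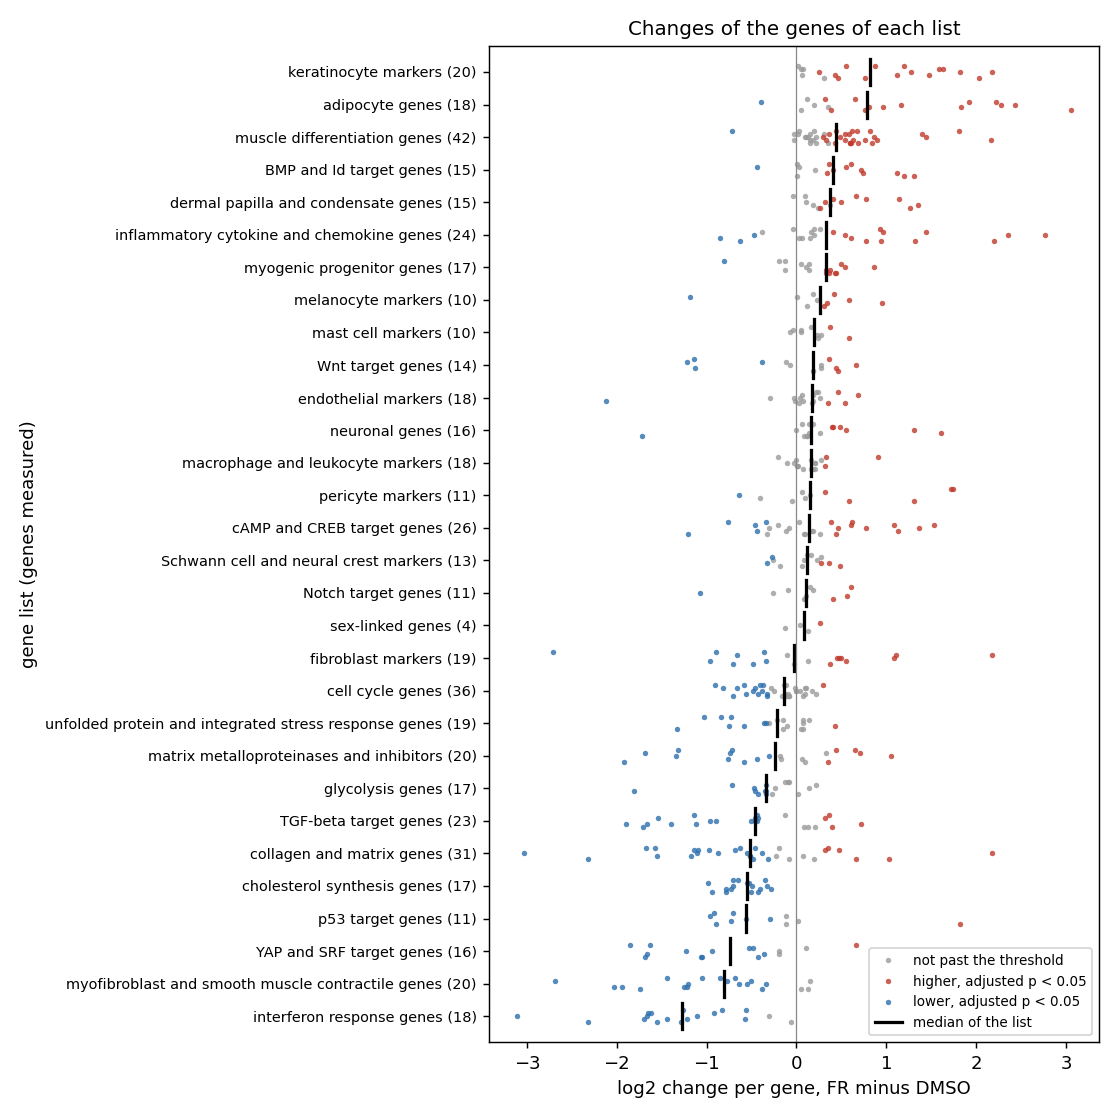
Log2 change, FR minus DMSO, of each measured member of the 30 gene lists, 1 point per gene, coloured by the limma call at adjusted p under 0.05, with the median of each list as a black bar. The medians run from -1.27 for the interferon response genes to 0.82 for the keratinocyte markers.

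Small changes depended on the level of a gene. The median change over all genes was 0.053. In 10 equal bins of mean level it was 0.077 in the dimmest bin, highest at 0.144 in the bin of mean level 5.07 and lowest at -0.099 in that of 7.66. The 1027 olfactory receptor genes, which serve as a measure of background, had a median DMSO level of 4.01 and a median change of 0.139, and 102 of them passed as higher and 6 as lower, so small rises of dim genes are also called in background probe sets. The median array value of FR was also above that of DMSO. With each array centred on its median, 1880 genes were higher and 3447 lower, so the share of higher genes among those that changed went from 48.0% to 35.3%. With dim genes left out, 2129 were higher and 3250 lower, 39.6% higher. The share moved less with quantile normalization (46.2%) and cyclic loess (45.8%). The 2-fold counts moved less, to 297 higher and 339 lower with centring.

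**Figure D3:**
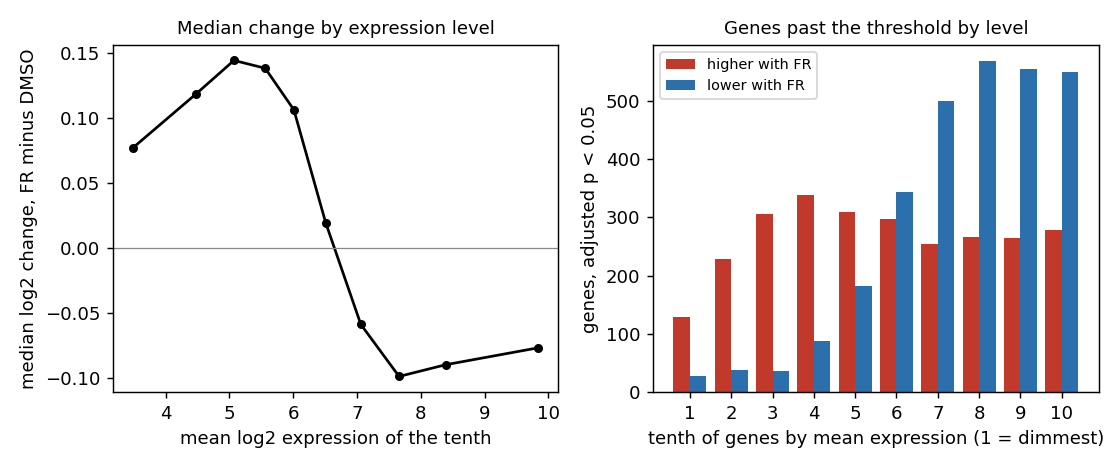
Median log2 change of the genes in each of 10 bins of mean expression (left) and the numbers of genes past adjusted p 0.05 in each bin (right, red higher with FR, blue lower). The median is above 0 in the 6 dimmest bins and below 0 in the 4 brightest.

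Of the 30 lists, 19 passed with the preset correlation, 8 up and 11 down; with a correlation estimated per list, camera passed 0, with 9 at unadjusted p under 0.05, while fry passed 24 by direction. Only the pair of compounds was tested, so their separate effects cannot be told from these arrays.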

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

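The tests for mature muscle fibre RNA and for leukocytes were chosen only after the results were seen. Outside the genes tested, 12146 probe sets have no gene in the annotation, and they showed signal too: 95 were at least 2-fold higher with FR and 98 at least 2-fold lower, among 569 higher and 618 lower in all. They are not among the 5559 genes or in any gene list, and no explanation was tested for them.

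The rise of muscle differentiation genes in dermal cells is 1 of 3 patterns weighed. An upward shift of dim probe sets on the FR arrays is argued against by the random lists matched on level: the upper end of their central 95% was 0.167, and the median of the muscle list was 0.435. Carry-over of mature fibre RNA was tested on 6 adult fibre genes, of which the largest change was 0.145 (Ckm), below the smallest among 7 genes of embryonic and regenerating muscle, 0.43 (Chrng). Both sets were picked after their values were seen, and Myh1, Acta1 and Tnni2, which adult fibres also use and which are in neither set, rose by 0.84, 0.59 and 0.76, so this test excludes nothing and carry-over cannot be told apart from an effect of FR. It stays open whether FR may have raised these genes in cells already committed to muscle, in other dermal cells, or through a larger share of muscle precursors, since the arrays average over all cells.

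Keratinocyte markers were higher with FR in all 3 arrays. A larger share of keratinocytes is in line with a separate set of epithelial genes, whose median rose above that of matched random lists: 0.342 against an upper end of 0.183, with 15 of 28 measured genes higher and 1, Jup, lower. A lower share of fibroblasts that would lift every other cell type alike was tested on 19 markers above the median level of all genes. They are listed for 6 other cell types (endothelial, pericyte, Schwann, melanocyte, leukocyte and mast). Their median change was 0.037 with an upper quartile of 0.20, below the lower quartile of 0.56 of the 7 keratinocyte markers above that level. The endothelial, melanocyte, leukocyte and mast lists had median DMSO levels of 5.05, 5.52, 4.76 and 4.21, under the background level of 5.65. Those of pericyte and Schwann markers were 5.91 and 6.49. The arrays do not show which cells gave the signal of the 19 markers, so this test excludes nothing. Adipocyte, muscle and neuronal lists, which rose, were not in that set. It could not be separated here whether fewer fibroblasts contributed, or whether FR spared or expanded keratinocytes. Nor could changed expression in keratinocytes already present, or epithelial genes turned on in dermal cells, be told apart.

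Interferon response genes were lower with FR, and no single array carried the difference: without any 1 array the mean change of the list stayed at -1.150 or further from 0, against -1.29 with all arrays. Loss of leukocytes cannot be told apart from an effect of FR: the median DMSO level of their markers, 4.76, lay 0.752 above that of olfactory receptor genes but under the 95th percentile of those genes, 5.65, where a fall could not show. Interferon activity that differed between cultures for reasons other than the treatment cannot be told apart from an effect of FR, because the labels give no batch that crosses the groups. The largest range within a group was 0.434, in DMSO, where replicate 1 lay at 7.76 and the others at 7.33 and 7.38, and the gap between groups was 1.29.

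Other splits of the 6 arrays into 3 and 3 are too few for a share under 0.05, since there are 10. The real split gave 5559 genes and 624 genes with a 2-fold change, and the highest of the other splits gave 0 for both, so that 1 of 10 splits reached each count. For gene lists, the real split gave 19 and the highest of the others 14, and again 1 of 10 splits reached the count. The other splits mix the groups, so much of their list count can come from the treatment itself.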

How the results depend on the processing

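The cyclic loess alternative was chosen after seeing the data, and the others before. The count of 5559 genes stayed within 1.5 times under every alternative but 2: a test against a log2 change of 0.5 gave 842 (412 higher, 430 lower), by its stricter construction, and ordinary variance without moderation gave 3364 (1484 higher, 1880 lower), with fewer degrees of freedom per gene. The 2-fold count of 624 stayed within that range wherever it was computed, with 636 after centring, 608 after cyclic loess and 877 of all probe sets. The 19 lists became 0 with an estimated correlation, and were 17 to 21 under the alternatives that kept the preset one and 24 by fry. Of the 5559 genes, 4471 kept their call under cyclic loess, 4764 after centring and 3137 with ordinary variance. The test against a log2 change of 0.5 kept 842. Without any 1 array, 3914 to 4904 kept their call. With dim genes left out, 4385 kept it, where only 11385 genes were tested. Under each of these, 0 passed in the opposite direction.

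Without any 1 array the count of genes ranged from 4033 to 5914 (higher 1803 to 2975, lower 2230 to 2939), the 2-fold count from 612 to 631 (higher 309 to 329, lower 284 to 321) and the lists from 18 to 21. With the replicate number as a block, 4977 genes (2311 higher, 2666 lower), 624 genes with a 2-fold change (325 and 299) and 19 lists passed. Samples with the same number did not deviate together (r = -0.073, 0.047 and -0.034 for numbers 1, 2 and 3, across genes), and not every sample correlated best with its own number, so the numbers are not taken to pair the samples.

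The direction of the test turned in 3 lists, none of them past the threshold: fibroblast markers with cyclic loess (adjusted p = 0.973), endothelial markers with dim genes left out (0.6) and Wnt target genes on ranks (0.677). The mean change of endothelial markers, 0.057, also turned to -0.019 with quantile normalization and -0.039 with cyclic loess, and that of fibroblast markers, -0.022, to 0.001 without FR replicate 3. The cause was not tested. Of 136 named genes, 127 kept direction and call under all alternatives run on them. Pax7, Nrarp, Gfra3, Ncam1, Xist, Cd74, Fcer1g, Hdc and Cnp lost the call under at least 1 of these. Of 30 lists, 4 kept direction and call under all alternatives run on them. Neither named genes nor lists were compared under array weights, ordinary variance, the test against a minimum change or every probe set tested. Ordinary variance and the minimum change cut the count of genes most. With dim genes left out, 121 of the 136 named genes were tested, and these kept their call. The others were not tested there. The signal of dim genes over background limits what their small changes can show.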

Other observations

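The scan of gene families was chosen after seeing the data, with families formed from the letters that open a symbol. Of 233 families tested with camera, 30 passed, 12 up and 18 down, and none passed with an estimated correlation (adjusted p = 0.814 for each). Of the 30, 30 stayed past the threshold with centring, 18 (6 up, 12 down) with quantile normalization and 11 (2 up, 9 down) with cyclic loess. Those described here were picked from the 11. Of 35 Vps genes, which act in sorting to endosomes and lysosomes, 17 fell and none rose (median -0.25, adjusted p = 5.6e-05), with Vps13a 2.19-fold lower and Vps13c 1.97-fold lower. Of 30 Snx genes, which encode sorting nexins, 14 fell and 1, Snx18, rose (adjusted p = 0.000114), and Snx24 was 3.03-fold lower. Of genes with symbols opening in Rab, mostly small GTPases of vesicle traffic, 26 of 70 fell and 4 rose (adjusted p = 0.000718), led by Rab7b, at least 3.41-fold lower, and Rab31, 2.51-fold lower. The annexins, calcium-dependent membrane-binding proteins, fell in 8 of 12 cases with none higher (median -0.52, adjusted p = 0.000406), with Anxa3 2.34-fold and Anxa4 2.20-fold lower.

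Other families rose. Of 13 Sprr genes, cornified envelope precursors of keratinocytes, 9 rose and none fell (median 0.44, camera adjusted p = 0.00109). Sprr1b was 2.98-fold and Sprr1a 2.52-fold higher, beside the rise of keratinocyte markers with FR. Of the 13, 8 lay under the background level of 5.65 in both groups, where small rises were also called in olfactory receptor genes. Of 12 genes with symbols opening in Bmp, 6 rose and none fell (median 0.29, camera adjusted p = 0.0111), and 3 of the 12 lay under that level in both groups. The largest rises were those of Bmp4, 2.81-fold, and Bmp7, 1.79-fold. The medians of all 6 families lay outside the central 95% of random lists matched on level. The direction and call of each held with quantile normalization, centring and cyclic loess. The 6 were picked from families that had passed in these same arrays, so neither result is separate support. Of the ligand genes Tgfb2 and Tgfb1, both chosen after their values were seen, Tgfb2 rose by 2.74 (level 6.26 to 9.01, adjusted p = 3.61e-08) and Tgfb1 fell by 0.96. No explanation was tested for these values.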
